A study of Mus musculus with 19 samples.

How the data were processed

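RNA from brains of female C57BL/6 mice was profiled on 15 spotted arrays with a pair of dyes and on 4 Affymetrix arrays. The 15 spotted arrays fall into 3 groups of 5. The groups are brains on day 6 after infection with Plasmodium berghei ANKA (PbA), on day 6 after infection with P. berghei K173 (PbK), and on day 14 after infection with PbK. Per the labels, the infected sample carried Cy5 and the uninfected control Cy3 on every spotted array, so no dye was swapped and a gene-specific dye effect cannot be separated from infection on these arrays. The 4 Affymetrix arrays hold 1 sample each from the uninfected, PbA day 6, PbK day 6 and PbK day 14 groups.

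For the spotted arrays the authors deposited 1 log2 ratio of infected over uninfected signal per spot and array. Limma is the only program in the submitters' processing notes, with no version. Background correction, normalization within arrays and the rule that left cells empty are not given in the sources used here. The log base is not written either and was taken as 2 because limma's log ratios are log2, so every change given for these arrays rests on that reading. The direction was taken from the dyes in the labels. The median absolute log2 ratio was 0.341 on each of the 15 arrays, so the deposited values had already been brought to one scale by that measure. Array medians lay between -0.0587 and 0.035. For the Affymetrix arrays the authors deposited a linear intensity per probe set, after one-cycle biotin labelling per the labels. From the values, the mean after trimming 2% at each end was 500 on each array. The summary algorithm is not given in the sources used here.

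The series text states that RNA of 5 mice per group was pooled into a single sample for hybridisation, whereas the labels number 5 spotted arrays per infected group and describe brains homogenised one by one. Which arrays held pools therefore stays open. All p-values measure the spread between arrays, which may be technical. The uninfected sample served as the reference on every spotted array and was not hybridised against itself, so a test of a ratio against 0 leaves out the spread between control mice.

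Probe names came from GEO's platform annotation with symbols updated through Entrez identifiers, which matched for 96% of the spotted-array entries and 99.4% of the Affymetrix entries. Of 23040 spots, 16874 had 1 gene, 134 several and 6032 none listed. Of 45101 probe sets, 34958 had 1 gene, 932 several and 9211 none listed. Spots with several genes or none were tested as unnamed spots. Spots of one gene were averaged. Among 831 genes with several spots, 62, 11 and 17 had a called spot in PbA day 6, PbK day 6 and PbK day 14, and 23, 4 and 6 of those had spots of opposite sign.

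Arrays carried a value on 36.6% to 98.3% of spots, and their number, 5 per group, limits the precision. Features with a value on at least 3 arrays of every group were tested, which left 16422 of 21262 features, 12631 of them named genes. A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8, for input, and moderated with a prior of 2.64 degrees of freedom over a median of 11 residual ones. Each group mean was tested against 0 and each pair of groups against each other, both two-sided. P-values were adjusted by the Benjamini-Hochberg method over all features, and a feature was called at an adjusted p under 0.05. Errors of log2 values are standard errors of this model.

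Before the data were examined, 27 gene lists were fixed. They covered interferon-stimulated genes, interferon-gamma-induced GTPases and regulators, MHC class I and class II antigen presentation, cytokines and chemokines, complement, reactive gliosis, endothelial activation, hypoxia and glycolysis, glucocorticoid-responsive genes, heat-shock proteins, apoptosis, the kynurenine pathway, iron and haem handling, the cell cycle, immediate early genes, oxidative phosphorylation and cytosolic ribosomal proteins. They also held markers of T and NK cells, B cells, neutrophils and monocytes, erythroid cells, microglia, astrocytes, endothelium, neurons and oligodendrocytes. Lists were tested against all other genes with limma's cameraPR at a preset correlation of 0.01, two-sided and adjusted over the 27 lists of a comparison. It was given z-scores with the p-values of the moderated statistics, the form that limma's camera uses internally. CameraPR replaced camera itself, which was planned and cannot take missing values. It was first given the moderated statistics as they were, and the z-scores were chosen after those results had been seen. The first form is kept as an alternative. The correlation was also estimated from the residuals, and fry was run on the 6098 features measured on all 15 arrays. The samples, groups, lists, rule for named genes and tests other than this form of the list test were chosen before the data were examined, as were most alternatives. 3 further lists, for the anterior pituitary, the choroid plexus and the meninges, and the ratios between infected Affymetrix arrays were added afterwards.

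Named genes were taken by a fixed rule. For each infected group against control, it takes the 10 highest and 5 lowest called genes with one sign on every array. For each pair of infected groups it takes up to 8 in each direction whose arrays do not overlap, and for each list up to 4 called members, or 2 members where none was called. On the Affymetrix arrays it takes the 10 highest and 5 lowest ratios. It always takes 13 genes, of which 10 were tested on the spotted arrays and 2 were not analysed here. A gene named outside this rule is said to have been chosen after its values were seen.

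The Affymetrix values were used as log2(signal + 16), with the probe set of highest mean signal for each gene. Genes in the upper 60% of highest signal entered, which kept 10916 of 18194. With 1 array per group there is no error and no test. Genes are counted at a log2 ratio of at least 1 in size, on the log2(signal + 16) scale, which understates changes of weak genes. A list's median was placed among 10000 random lists of the same size and similar mean signal.

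The model was tested on simulated data in which 100 of the 16422 features each were given a log2 change of 1 or 2. For PbA day 6 against control, 46% and 86% of them were recovered among 138 calls, 6 of which were unchanged features. For PbA day 6 against PbK day 6, 28% and 69% were recovered among 102 calls, 5 of which were unchanged. A simulation of PbK day 6 against control with no change gave 0 calls. In the simulated list test, the 1 list shifted by 0.5 was the only list of 27 past the threshold. Genes were simulated independently of each other and without an error of the reference. The simulation therefore does not cover correlated genes or the shared reference.

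Alternatives covered the replicate number as a block, the scaling between arrays, the treatment of several spots and of missing values, the arrays in the fit, array weights, the variance estimate, the threshold, and leaving out each array of the groups compared in turn. For the Affymetrix arrays they covered the pseudocount, the signal filter, the scaling and the choice of probe set. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.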

Results

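Gene expression was measured in brains of C57BL/6 mice infected with one of 2 lines of the rodent malaria parasite Plasmodium berghei. PbA, the ANKA line, causes cerebral malaria in this mouse strain, and PbK, the K173 line, was used here as an infection without that syndrome. The comparisons ask which transcripts changed in the brain on day 6 of PbA infection, which also changed on day 6 and day 14 of PbK infection, and which differed between the infections. Spotted arrays gave log2 ratios of infected over uninfected brain for 5 arrays in each of the 3 infected groups. Affymetrix arrays gave signals for 1 sample from each infected group and 1 uninfected sample. Values were present on 36.6% of spots on the sparsest spotted array, PbA replicate 4, and on 98.3% on the fullest, PbK day 14 replicate 4.

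The spotted arrays resembled each other only moderately across features, which are not independent replicates. Pearson's r over all pairs of arrays had a median of 0.344 and ran from 0.0589 to 0.616. The median was 0.358 within groups and 0.338 between them. A set of 5 arrays (PbA replicates 2, 4 and 5, PbK day 6 replicate 3 and PbK day 14 replicate 2) correlated at a median of 0.524 across groups (7 pairs). Their median r with those of the other 10 arrays that belong to a different group was 0.254 (36 pairs). No label names what these 5 arrays share.

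On day 6 of PbA infection, interferon-induced genes and genes of antigen presentation were higher in infected than in uninfected brain. Ifitm3, an interferon-induced membrane protein that restricts viral entry, rose by 2.68 ± 0.344 log2 units (SE, 5 of 5 arrays, adjusted p = 0.00256). B2m, the light chain of MHC class I molecules, rose by 2.43 ± 0.267 (5 of 5 arrays, adjusted p = 0.00162). Gzmb, a cytotoxic granule protease of T and NK cells, rose by 2.20 ± 0.334 (4 of 4 arrays with a value, adjusted p = 0.00901). Gfap, the intermediate filament of reactive astrocytes, rose by 1.14 ± 0.138 (5 of 5 arrays, adjusted p = 0.00225). Mt1, a metal-binding stress protein, rose by 1.26 ± 0.158 (5 of 5 arrays, adjusted p = 0.00241). Each of these 5 genes kept its call when any single PbA array was left out.

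The 16 measured interferon-gamma-induced GTPases and regulators had a median of 1.32 in PbA infection, and all 16 lay above 0. 4 of them rose by the test over all genes, and 11 when adjusted over the list alone (list adjusted p = 1.51e-08). They included the immunity-related GTPases Igtp (2.29 ± 0.377) and Iigp1 (2.04 ± 0.276) and the transcription factors Irf1 (1.85 ± 0.261) and Irf8 (1.30 ± 0.212). Of 32 interferon-stimulated genes, 12 rose and 1 fell, with 19 higher and 2 lower when adjusted over the list alone (median 0.82, list adjusted p = 8.32e-09). This list missed the threshold at adjusted p = 0.0595 with an estimated correlation. Trim30a reached 2.48 ± 0.324, Samd9l 2.39 ± 0.544 and Ifit1 2.11 ± 0.421, whereas Dhx58, a cytosolic RNA sensor, fell by 1.72. Dhx58 was chosen after its values were seen. Of 15 MHC class I genes, 6 rose, and 8 when adjusted over the list alone (median 0.79, list adjusted p = 5.67e-08). H2-Q7 rose by 2.28 ± 0.422, H2-Q10 by 2.10 ± 0.286 and H2-D1 by 1.76 ± 0.307. Of 6 MHC class II genes, 1 rose, and 3 when adjusted over the list alone (median 0.76, list adjusted p = 0.0188). This list missed the threshold at adjusted p = 0.107 with an estimated correlation, and at 0.0875, 0.0509 and 0.0525 without PbA replicates 1, 2 and 5. The called member was Ctss, a lysosomal protease that processes the invariant chain, at 1.58 ± 0.329.

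**Figure D1:**
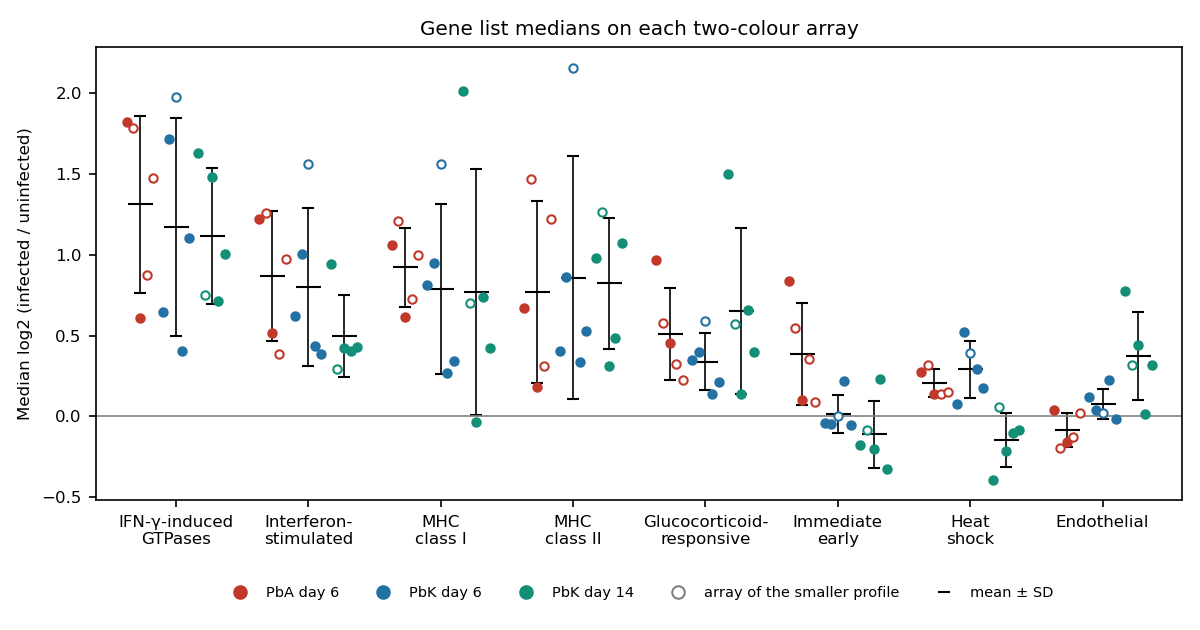
Median log2 ratio (infected over uninfected) of 8 gene lists on each of the 15 spotted arrays, coloured by group, with the mean and SD of the 5 arrays; open points are the 5 arrays that correlate with each other across groups. The mean of the array medians of the interferon-gamma-induced list was 1.31, 1.17 and 1.12 in PbA day 6, PbK day 6 and PbK day 14.

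Other groups of genes also moved in PbA brains. Of 20 glucocorticoid-responsive genes, 3 rose, and 5 when adjusted over the list alone (median 0.54, list adjusted p = 0.000813, and adjusted p = 0.0595 with an estimated correlation). Besides Mt1 these were Cdkn1a, a cell cycle inhibitor, at 1.29 ± 0.224 and Tsc22d3, a glucocorticoid-induced leucine zipper protein, at 0.99 ± 0.221. Of 21 cell cycle genes, 4 rose, and 7 when adjusted over the list alone (median 0.61, list adjusted p = 0.00259). They were the replication genes Pcna (1.26 ± 0.295), Mcm2 (1.03 ± 0.196), Tk1 (0.70 ± 0.145) and Mcm5 (0.67 ± 0.139). All 4 lost their calls without PbA replicate 5. Pcna also did without replicates 2 and 4, Mcm5 without replicate 2 and Tk1 without replicate 4. Of 18 immediate early genes, 1 rose (Btg2, 0.87 ± 0.224, 4 of 5 arrays), and 7 when adjusted over the list alone (median 0.30, list adjusted p = 0.00259). That list gave adjusted p = 0.209 with an estimated correlation, and 0.138 without PbA replicate 1. In all, 11 of 27 lists passed in PbA, all upward, against 5, 7 and 7 without PbA replicates 1, 2 and 5. With an estimated correlation 3 passed, the interferon-gamma-induced, MHC class I and cell cycle lists, each at adjusted p = 0.0317.

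Glial and vascular genes changed as well. Of 15 astrocyte markers, 2 rose, Gfap and the gap-junction gene Gjb6 (0.72 ± 0.124), with 6 higher and 1 lower when adjusted over the list alone (median 0.16, list adjusted p = 0.0434). Adjusted p = 0.0595 with an estimated correlation for that list, and it was 0.159, 0.0863 and 0.0696 without PbA replicates 1, 3 and 5. Of 15 reactive gliosis genes, 2 rose, Gfap and the endotoxin co-receptor Cd14 (0.98 ± 0.208), also 2 when adjusted over the list alone (median 0.27, list adjusted p = 0.0364). Adjusted p = 0.191 with an estimated correlation for the gliosis list, and it was 0.129 and 0.193 without PbA replicates 1 and 2. Of 14 myelin genes, 2 rose, with 5 higher and 1 lower when adjusted over the list alone (median 0.14, list adjusted p = 0.0434, and adjusted p = 0.229 with an estimated correlation). They were Sox10 (0.82 ± 0.190) and Cldn11 (0.62 ± 0.158). Cldn11 lost its call whichever PbA array was left out, and Sox10 without PbA replicates 2, 4 and 5. The myelin list also missed the threshold without PbA replicates 1, 2, 3 and 5, at 0.0562, 0.0671, 0.0687 and 0.0879, and with arrays centred on their median, at 0.0502. Of 25 cytosolic ribosomal protein genes, only Rpl8 rose (0.58 ± 0.126), also 1 when adjusted over the list alone (median 0.14, list adjusted p = 0.033, and adjusted p = 0.411 with an estimated correlation). Without PbA replicates 1, 2, 3 and 5 the ribosomal list gave 0.254, 0.0506, 0.0863 and 0.063. Of 16 endothelial markers, Ly6c1 (1.37 ± 0.204) and Emcn (1.22 ± 0.226) rose and the transporter Slco1a4 fell by 0.94, with no shift of the list (median -0.20, mean 0.02, list adjusted p = 0.981).

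Chemokines responded singly. Cxcl11 rose by 2.34 ± 0.428, Ccl2 by 1.32 ± 0.318 (4 of 5 arrays) and Ccl12 by 1.32 ± 0.278. Ccl2 lost its call without PbA replicates 2, 4 and 5, and Ccl12 without replicates 1, 2 and 5. Il1b fell by 0.97 ± 0.213 (3 of 3 arrays with a value, adjusted p = 0.0401) and lost its call without PbA replicates 4 and 5. The cytokine list of 27 genes did not shift (median -0.04, mean 0.23, list adjusted p = 0.38). Laptm5, a lysosomal protein of leukocytes, rose by 1.10 ± 0.193 and Vcam1, an endothelial adhesion molecule, by 1.13 ± 0.229. Among the genes named in advance, values that missed the threshold were 0.79 for Cxcl10 (4 of 5 arrays), 0.68 for Icam1, 0.83 for Hmox1, 1.26 for Fkbp5 (5 of 5 arrays), -0.25 for Tnf, -0.72 for Ido1 and 0.30 for Cd8a. The lowest called genes were Apoc1, an apolipoprotein, at -5.34 ± 0.554, Rhbdf1 at -4.56 ± 0.972, Ulk3 at -3.45 ± 0.334, 2310022A10Rik at -3.24 ± 0.551 and Fastkd3 at -3.11 ± 0.344.

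In all, limma called 585 of 16422 features in PbA day 6 against control, 385 higher and 200 lower, and 501 of them were named genes. Of the 46 named called genes of the fixed rule, 18 kept the call without each PbA array wherever they were still tested. Cd14, 1 of the 18, had a value on 3 PbA arrays only, so leaving out any of those left it untested. Leaving out PbA replicates 2, 4 or 5 left 188, 320 or 106 called features, and 22 of 45, 12 of 46 and 26 of 44 named called genes still tested lost their call. Among those that ended without replicate 5 were Ifit1, Igtp, H2-Q7, Ctss and Cxcl11. A fit to the 5 PbA arrays alone called 0 features with limma, with 3768 at an unadjusted p under 0.05, and a fit with group means within the 10 arrays outside the correlated set, chosen after the data were seen and leaving 2 PbA arrays, called 3. Array weights gave 1524.

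**Figure D2:**
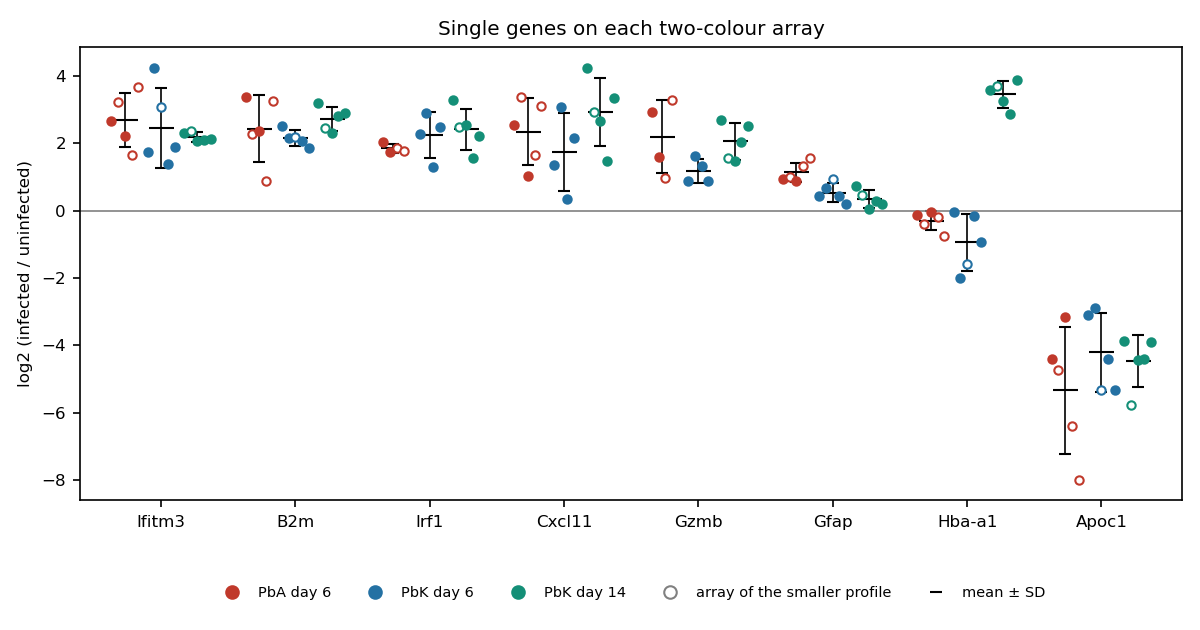
Log2 ratio (infected over uninfected) of 8 genes on each of the 15 spotted arrays, with the mean and SD per group; open points are the 5 arrays that correlate with each other across groups. Ifitm3, B2m and Irf1 lay above 0 on every array with a value, Hba-a1 was high only on the PbK day 14 arrays, and Apoc1 lay below 0 on every array.

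On day 6 of PbK infection, interferon-induced and MHC class I genes were higher than in uninfected brain as well. Gbp4, an interferon-induced guanylate-binding protein, rose by 2.75 ± 0.575 (5 of 5 arrays, adjusted p = 0.0477) and Ifitm3 by 2.46 ± 0.344 (5 of 5 arrays, adjusted p = 0.00922). Irf1 rose by 2.24 ± 0.261 (4 of 4 arrays, adjusted p = 0.00689), B2m by 2.15 ± 0.267 (5 of 5 arrays, adjusted p = 0.00689) and Ly6c1 by 1.499 ± 0.204 (5 of 5 arrays, adjusted p = 0.00922). Irf1, B2m, Ly6c1 and Apoc1, which fell by 4.204, kept their calls when any single PbK day 6 array was left out. Gbp4, in contrast, lost its call whichever of the 5 arrays was left out.

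Of the 16 interferon-gamma-induced genes, 4 rose in PbK day 6, and 12 when adjusted over the list alone (median 1.24, list adjusted p = 2.07e-10). The 4 were Gbp4, Irf1, Gbp3 (1.36 ± 0.286) and Irf8 (0.98 ± 0.190), and Gbp3, like Gbp4, lost its call without any single array. Of 32 interferon-stimulated genes, 4 rose, with 19 higher and 2 lower when adjusted over the list alone (median 0.76, list adjusted p = 2.07e-10). The 4 were Ifitm3, Ifit1 (2.43 ± 0.377), the nucleic acid sensor Zbp1 (1.75 ± 0.335) and Irf9 (1.45 ± 0.227). Of 15 MHC class I genes, B2m, H2-D1 (1.97 ± 0.307) and H2-Q10 (1.95 ± 0.286) rose, and 5 when adjusted over the list alone (median 0.55, list adjusted p = 5.42e-06). Of 18 microglia and macrophage markers, 0 were called by limma, and 2 rose when adjusted over the list alone (median 0.25, list adjusted p = 0.0328). The microglial members Cd52 and Mpeg1 stood at 1.37 and 0.85. This list missed the threshold without PbK replicates 3 and 4, at 0.104 and 0.0582. These 4 lists kept the threshold with an estimated correlation, at 0.0197, 0.049, 0.049 and 0.049 in the order given.

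A pair of further lists passed in PbK day 6 only at the preset correlation. Of 20 glucocorticoid-responsive genes, Cdkn1a rose (1.07 ± 0.224), and 5 when adjusted over the list alone (median 0.24, list adjusted p = 0.0228, and adjusted p = 0.212 with an estimated correlation). Without PbK replicates 1 and 3 it gave 0.0902 and 0.104. Of 17 heat-shock proteins and chaperones, limma called 0 over all genes and 0 when adjusted over the list alone (median 0.29, list adjusted p = 0.00499, and adjusted p = 0.122 with an estimated correlation). Their members Pdia4 and Hspb1 stood at 0.70 and 0.64. Gfap (0.53, adjusted p = 0.0779), Gzmb (1.18, adjusted p = 0.0993), Icam1 (1.10) and Mt1 (0.36) missed the threshold, as did Cxcl10 (0.22), Tnf (-0.32), Ido1 (-0.10), Cd8a (-0.49), Hmox1 (-0.11) and Fkbp5 (0.86). The 6 class II genes had a median of 0.75 and did not pass as a list (list adjusted p = 0.197). Of them Ifi30, a lysosomal thiol reductase, fell by 2.01, and 4 were higher and 1 lower when adjusted over the list alone. The lowest called genes were Apoc1, 4930532I03Rik at -3.34 ± 0.441, 2310022A10Rik at -2.80 ± 0.551, 4930553E22Rik at -2.80 ± 0.471 and the glycolytic enzyme Tpi1 at -2.77 ± 0.497.

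Limma called 98 features in PbK day 6 against control, 35 higher and 63 lower, of which 67 were named genes. Quantile scaling left 45, 24 higher and 21 lower, so that the majority turned, and array weights gave 1083. Leaving out PbK day 6 replicates 1 to 5 left 54, 319, 10, 22 and 26, and without replicate 3 the calls of 15 of the 19 named called genes still tested ended, among them Ifitm3 (adjusted p = 0.0544), H2-D1 and H2-Q10 (adjusted p = 0.0604 each). A fit to the 5 PbK day 6 arrays alone called 0 features with limma, with 2267 at an unadjusted p under 0.05, and group means within the 10 arrays outside the correlated set, chosen after the data were seen, gave 8.

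On day 14 of PbK infection, haemoglobin joined the interferon-induced and antigen-presentation genes. Hba-a1, an alpha-globin gene of red blood cells, rose by 3.45 ± 0.244 (5 of 5 arrays, adjusted p = 1.02e-05). H2-Q10, a class I molecule, rose by 2.77 ± 0.286 (5 of 5 arrays, adjusted p = 0.00035) and B2m by 2.72 ± 0.267 (5 of 5 arrays, adjusted p = 0.000262). Irf1 rose by 2.41 ± 0.233 (5 of 5 arrays, adjusted p = 0.000432) and Gzmb by 2.06 ± 0.299 (5 of 5 arrays, adjusted p = 0.00838). Ly6c1 rose by 1.96 ± 0.204 (5 of 5 arrays, adjusted p = 0.00035) and Mt1 by 1.44 ± 0.158 (5 of 5 arrays, adjusted p = 0.000486). All of these kept their calls when any single PbK day 14 array was left out.

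Of the 16 interferon-gamma-induced genes, Gbp4 (3.01 ± 0.575), Irf1 and Irf8 (1.23 ± 0.190) rose on day 14, and 11 when adjusted over the list alone (median 1.21, list adjusted p = 9.07e-11). Of 15 MHC class I genes, H2-Q10, B2m, H2-D1 (2.02 ± 0.307) and H2-Q2 (1.93 ± 0.369) rose, and 6 when adjusted over the list alone (median 0.56, list adjusted p = 1.35e-08). Of 6 class II genes, Cd74, the invariant chain, rose by 2.66 ± 0.426, and 3 rose when adjusted over the list alone (median 0.72, list adjusted p = 0.00174). Of 32 interferon-stimulated genes, only Ifitm3 (2.19 ± 0.344) was called, with 8 higher and 2 lower when adjusted over the list alone (median 0.61, list adjusted p = 4.9e-08). This list missed the threshold at adjusted p = 0.0649 with an estimated correlation. Of 20 glucocorticoid-responsive genes, Mt1 and Cdkn1a (1.41 ± 0.224) rose, and 8 when adjusted over the list alone (median 0.64, list adjusted p = 1.35e-08). Of 16 endothelial markers, Ly6c1 and the TGF-beta co-receptor Eng (0.71 ± 0.110) rose, and 3 when adjusted over the list alone (median 0.25, list adjusted p = 0.000974). Of 25 cytosolic ribosomal protein genes, limma called 0 over all genes, and 3 rose when adjusted over the list alone (median 0.23, list adjusted p = 1.35e-08). Their members Rps3 and Rps23 stood at 0.72 and 0.56. In all, 9 of 27 lists passed, and 6 did with an estimated correlation.

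Neuronal markers shifted the other way on day 14. Of 22 neuronal markers, limma called 0 over all genes and 2 lower when adjusted over the list alone (median -0.14, list adjusted p = 0.0238, and adjusted p = 0.144 with an estimated correlation). The calcium sensor Vsnl1 stood at -0.51 and the neurofilament gene Nefm at -0.44. The neuronal list missed the threshold without PbK day 14 replicates 1 and 4, at 0.165 and 0.0526. Arc (-1.16 ± 0.240) and Homer1 (-0.60 ± 0.124), activity-induced genes of synapses, fell. Both lost their calls whichever PbK day 14 array was left out, as did Vcam1 and Aldoc, given below. Of 15 endothelial activation and coagulation genes, Vcam1 rose (1.00 ± 0.205), also 1 when adjusted over the list alone (median 0.18, list adjusted p = 0.0179, and adjusted p = 0.109 with an estimated correlation). Without PbK day 14 replicates 1 and 5 that list gave 0.0788 and 0.113. Of 10 erythroid markers, Hba-a1 alone was called, also when adjusted over the list alone, and the list did not pass (median -0.02, or 0.03 with quantile scaling, mean 0.43, list adjusted p = 0.0596). Fry, which tests members against no change and not against other genes, gave adjusted p = 1.97e-05 on those present on all arrays. Other called genes were the chemokines Cxcl11 (2.92 ± 0.428) and Ccl8 (0.97 ± 0.192), the neutrophil protein S100a8 (0.99 ± 0.191), Ctla2a (2.15 ± 0.432), Gjb6 (0.83 ± 0.124) and Aldoc (0.81 ± 0.171). Gfap (0.34), Icam1 (1.03), Fkbp5 (1.78, adjusted p = 0.0668), Cxcl10 (0.38), Tnf (-1.10), Ido1 (-0.85), Cd8a (-0.05) and Hmox1 (0.14) missed the threshold. The lowest called genes were Apoc1 (-4.48 ± 0.554), 2310022A10Rik (-4.25 ± 0.551), Ulk3 (-3.11 ± 0.386), Fastkd3 (-2.73 ± 0.308) and Larp1b (-2.70 ± 0.470).

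Limma called 129 features in PbK day 14 against control, 67 higher and 62 lower, of which 101 were named genes. Leaving out PbK day 14 replicates 1, 3 or 5 left 35, 57 or 57, and without replicate 1 the calls of 16 of the 31 named called genes ended, among them Cd74 (adjusted p = 0.0534), Irf8 (adjusted p = 0.0517) and Gbp4. A fit to the 5 PbK day 14 arrays alone called 16 features, array weights gave 210 and features measured on all 15 arrays 206.

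The infected groups shared calls. PbA day 6 and PbK day 6 had 20 higher calls in common, where independent lists of these sizes would share 0.821 and unchanged groups against the same reference shared 0.3 in simulation. PbA day 6 and PbK day 14 shared 36 (1.57 and 0.5), and PbK day 6 and PbK day 14 shared 18 (0.143 and 0.7). Lower calls in common numbered 16 (0.767 and 0.4), 33 (0.755 and 0.5) and 5 (0.238 and 0.7) in the same order of pairs. Across genes the group means had covariances of 0.246, 0.241 and 0.25, against simulated covariances of 0.0903, 0.0915 and 0.0905, with r of 0.625, 0.699 and 0.651 against simulated r of 0.44, 0.452 and 0.458. The simulated reference was taken as a pool of 5 mice. Part of the excess may come from the shared uninfected reference or from a gene-specific dye effect, which cannot be split from infection here. In all 3 groups 14 features were higher, among them 9 named genes: Ifitm3, B2m, H2-Q10, H2-D1, Irf1, Irf8, Ly6c1, Cdkn1a and 0610037M15Rik. A further 5 were lower in all 3, among them 4930402F06Rik, 2310022A10Rik, Ulk3 and Apoc1. One spot with no gene listed, spot 15820, stood at 3.80, 7.66 and 6.10 in the 3 groups and was chosen after its values were seen.

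The comparison of PbA day 6 with PbK day 6 asks what distinguishes the infection with cerebral malaria from one without it on the same day. No gene was called between them on the spotted arrays. Limma called 0 of 16422 features, with 1403 at an unadjusted p under 0.05, 911 of them higher in PbA. Mt1 stood 0.91 higher in PbA (adjusted p = 0.562), Gfap 0.61 higher (95% interval 0.19 to 1.02, adjusted p = 0.571), Gzmb 1.02 higher and Cxcl10 0.57 higher. The GTPase Igtp stood 1.45 higher and Trim30a 1.35 higher in PbA, whereas Gbp2 stood at a difference of -1.503. The Affymetrix samples differed the other way for Gbp2, with signals of 10280 in PbA day 6 and 3302 in PbK day 6. Genes of the fixed rule that also stood lower in PbA on the spotted arrays included Cd5 (-1.79), Dhx58 (-1.31), Abcg2 (-0.79), Ido1 (-0.62) and Icam1 (-0.42). The astrocyte transcription factor Sox9 stood 1.20 higher, the ribonucleotide reductase Rrm1 1.66 higher and the immediate early genes Fosb and Junb 1.60 and 1.38 higher. No adjusted p was below 0.562 among these genes. None of the 27 lists passed (0 by cameraPR and 0 by fry, with 4 at an unadjusted p under 0.05 by cameraPR). Without PbA replicate 3 or 5, 2 lists or 1 list passed.

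Between day 14 and day 6 of PbK infection, haemoglobin rose. Hba-a1 was 4.39 ± 0.345 higher on day 14 (95% interval 3.65 to 5.12, 5 of 5 arrays above 0 on day 14, adjusted p = 4.27e-05), and a spot with no gene listed, spot 6784, was 6.18 ± 0.514 higher (adjusted p = 9.98e-05). These were the 2 of 16422 features called, with 1101 at an unadjusted p under 0.05. Both stayed called without each array of the groups compared. Over all 25 alternatives, Hba-a1 lost its call in 1. The unnamed spot was chosen after its values were seen. Of 17 heat-shock proteins and chaperones, limma called 0 over all genes and 6 lower on day 14 when adjusted over the list alone (median -0.45, list adjusted p = 5.82e-05, and adjusted p = 0.0517 with an estimated correlation). The endoplasmic chaperone Pdia4 stood at -1.39 and Hsph1 at -0.90. Of 20 glucocorticoid-responsive genes, 0 were called over all genes and 1 was higher when adjusted over the list alone (median 0.32, list adjusted p = 0.0165, and adjusted p = 0.385 with an estimated correlation). Mt1 stood 1.09 higher on day 14 (adjusted p = 0.738). Without PbK day 6 replicates 4 and 5 and PbK day 14 replicate 1 that list gave 0.0603, 0.0584 and 0.185. Of 25 cytosolic ribosomal protein genes, 0 were called over all genes and 0 when adjusted over the list alone (median 0.14, list adjusted p = 0.00434, adjusted p = 0.389 with an estimated correlation, and 0.164 without PbK day 6 replicate 3). The erythroid list did not pass by cameraPR (median 0.07, mean 0.52, list adjusted p = 0.126).

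PbA day 6 and PbK day 14 differed in haemoglobin as well. Hba-a1 was lower in PbA at -3.75 ± 0.345 (adjusted p = 0.000345), as was spot 6784 at -5.78 ± 0.545 (adjusted p = 0.00047). These were the 2 features called. Of the 16422 tested by limma, 724 had an unadjusted p under 0.05, fewer than the share of 0.05 that chance alone would give. Group means within the 10 arrays outside the correlated set, chosen after the data were seen, called 0 by limma, with 559 at an unadjusted p under 0.05. In that fit, which leaves 2 PbA arrays, Hba-a1 stood at -3.47 (adjusted p = 0.071). Over all 25 alternatives, its call was lost in 2. Of 18 immediate early genes, 0 were called by limma over all genes and 1 was higher in PbA when adjusted over the list alone (median 0.56, list adjusted p = 2.19e-06, and adjusted p = 0.0769 with an estimated correlation). Fosb and Fos stood 1.53 and 1.52 higher in PbA. Of 16 endothelial markers, 0 were called over all genes and 1 was lower when adjusted over the list alone (median -0.38, list adjusted p = 0.000534, and 0.000386 with an estimated correlation). The drug and hormone transporter Slco1a4 stood at -0.96 and Emcn at 0.76. Of 17 heat-shock proteins and chaperones, 0 were called over all genes or over the list alone (median 0.43, list adjusted p = 0.000534, and adjusted p = 0.0769 with an estimated correlation), with Bag3 at 0.89.

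A further 3 of the 6 lists past the threshold between PbA day 6 and PbK day 14 passed at the preset correlation alone, and without PbK day 14 replicate 2 the 6 became 3. Cell cycle genes had a median of 0.36 (list adjusted p = 0.0338, and adjusted p = 0.158 with an estimated correlation), and 2 of 21 were higher when adjusted over the list alone. Interferon-stimulated genes had a median of 0.44 (list adjusted p = 0.0338, and adjusted p = 0.6 with an estimated correlation), and cytosolic ribosomal protein genes a median of -0.09 (list adjusted p = 0.0111, and adjusted p = 0.6 with an estimated correlation), with 0 members called by limma over all genes or over the list alone. Cell cycle genes gave 0.106, 0.121 and 0.187 without PbA replicates 1, 2 and 5, and 0.0819, 0.105, 0.0648 and 0.0668 without PbK day 14 replicates 2 to 5. Interferon-stimulated genes gave 0.353, 0.224 and 0.187 without PbA replicates 1, 2 and 5, and 0.137, 0.24 and 0.0961 without PbK day 14 replicates 2, 4 and 5. Ribosomal genes gave 0.0536 without PbA replicate 4 and 0.137 without PbK day 14 replicate 2. Gfap stood 0.80 higher in PbA (adjusted p = 0.848) and Mt1 at a difference of -0.18.

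On the Affymetrix arrays, with 1 array per group and hence no replicate check, interferon-gamma-induced genes stood highest in the PbA day 6 sample. The median log2 ratio over the uninfected sample was 4.59 in PbA day 6, 2.96 in PbK day 6 and 2.97 in PbK day 14 for 14 interferon-gamma-induced genes. It was 3.17, 1.80 and 1.90 for 30 interferon-stimulated genes, 2.65, 1.52 and 2.01 for 13 MHC class I genes and 2.52, 1.76 and 3.09 for 7 class II genes. All of these lay above the middle 95% of random lists. Among the GTPases, Gbp6 stood at 6.29, Igtp at 6.20 and Gbp2 at 6.15 in PbA day 6, and Gbp2 at 4.52 and Gbp6 at 4.42 in PbK day 6. The chemokine Ccl12 had signals of 1734 in PbA day 6 and 2.54 in the uninfected sample, and the granzyme Gzmb 2102 and 15.75. Both uninfected signals lay under the pseudocount of 16, which sets the size of these ratios. In PbK day 14 the pituitary hormone genes Gh (5.92) and Prl (5.40) stood above Lcn2 (5.13), an iron-binding acute-phase protein. A list of 4 anterior pituitary genes, added after the values were seen, stood at 3.59 in PbA day 6, 0.0889 in PbK day 6 and 4.28 in PbK day 14.

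**Figure D3:**
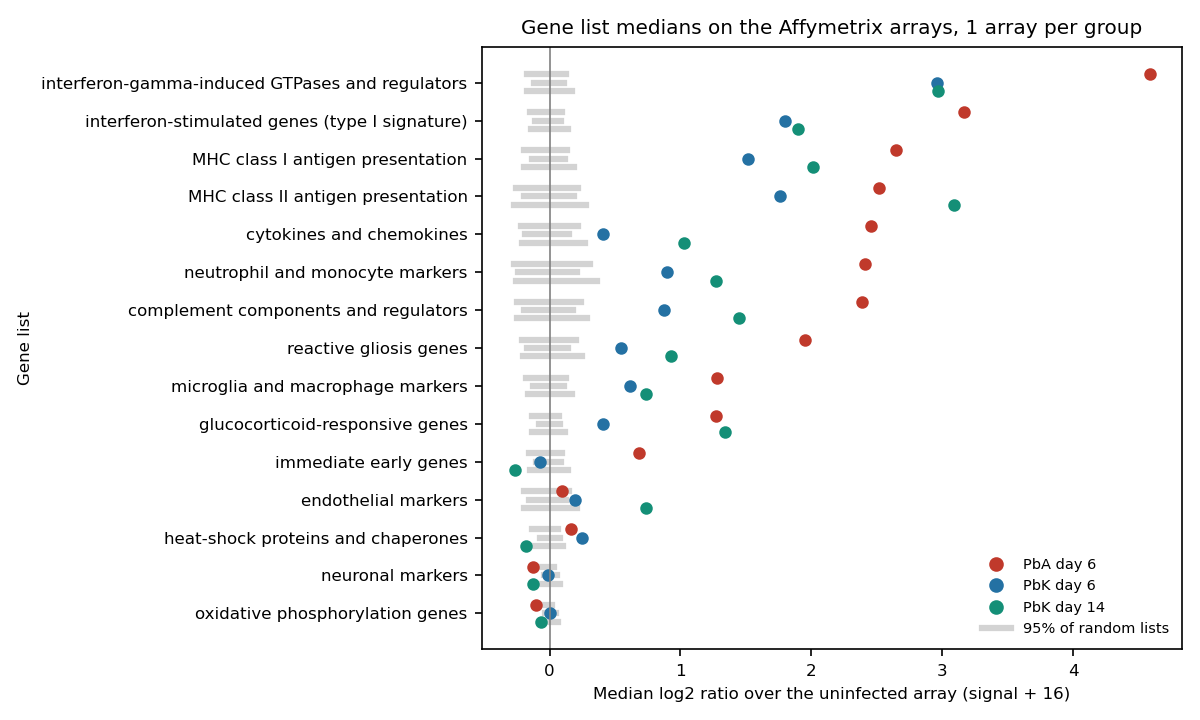
Median log2 ratio of 15 gene lists on the Affymetrix arrays, each infected sample over the uninfected sample (1 array per group, log2 of signal + 16), with grey bars for the middle 95% of random lists. Interferon-gamma-induced genes stood at 4.59 in PbA day 6 against 2.96 and 2.97 in the PbK samples, and endothelial markers at 0.741 in PbK day 14.

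Inflammatory and glial lists also stood higher in the PbA day 6 sample than in the PbK day 6 sample. Cytokines and chemokines had a median of 2.46 in PbA day 6 against 0.406 in PbK day 6 and 1.03 in PbK day 14. Reactive gliosis genes stood at 1.95, 0.548 and 0.926, microglia and macrophage markers at 1.28, 0.617 and 0.74, and immediate early genes at 0.683, -0.0722 and -0.262. Glucocorticoid-responsive genes stood at 1.27, 0.405 and 1.34. Between PbA day 6 and PbK day 6, the pituitary hormone genes Gh and Prl had the highest ratios, 4.56 and 4.54, so the PbA sample held a pituitary signal above that of the PbK day 6 sample. Ccl2 was 3.33 higher in PbA day 6 than in PbK day 6 and Cxcl10 2.95 higher (signals 4158 and 526). Ifng, the gene of interferon-gamma, had signals of 252 and 2.34, the latter under the pseudocount. Over the uninfected sample, PbA day 6 stood at 5.18 for Cxcl10, 2.97 for Icam1, 2.24 for Hmox1 and 2.06 for Gfap. The neuronal activity genes Npas4 and Fosb were 3.48 and 3.30 higher in PbA day 6 than in PbK day 14, and the endothelial gene Vwf was at -2.27. Endothelial markers stood at 0.0918, 0.191 and 0.741 over uninfected in PbA day 6, PbK day 6 and PbK day 14. Erythroid markers stood at -0.503, -0.669 and 0.585. The beta-globin gene Hbb-b2 had signals of 9.59 in PbA day 6, under the pseudocount, and 132.3 in the uninfected sample.

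Of 10916 genes, 384 stood at least 1 log2 unit higher and 63 at least 1 lower in the PbA day 6 sample than in the uninfected one, against 172 and 26 in PbK day 6 and 300 and 79 in PbK day 14. Between samples, the counts were 268 and 46 for PbA day 6 over PbK day 6, 132 and 65 for PbK day 14 over PbK day 6, and 208 and 83 for PbA day 6 over PbK day 14. Without the filter on low signal, the counts in both directions together came to 2124, 1752 and 2128 over uninfected.

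The platforms differed in the genes they placed high or low. Of the genes called on the spotted arrays and measured on both platforms, 253 of 396 (63.9%) had the same sign in PbA day 6, 25 of 44 (56.8%) in PbK day 6 and 58 of 75 (77.3%) in PbK day 14. Among genes called higher the share was 61.5%, 73.7% and 85.4%, and among genes called lower 70.5%, 44% and 67.6%. Of all genes measured on both platforms, 54.5%, 49.8% and 50.1% lay below 0 on the Affymetrix arrays. The 44% of lower calls in PbK day 6 thus lay under the share among all genes. Over 8162 genes, Pearson's r between the platforms was 0.244, 0.169 and 0.262 and Spearman's rho 0.148, 0.0699 and 0.219, across genes, which are not independent replicates.

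**Figure D4:**
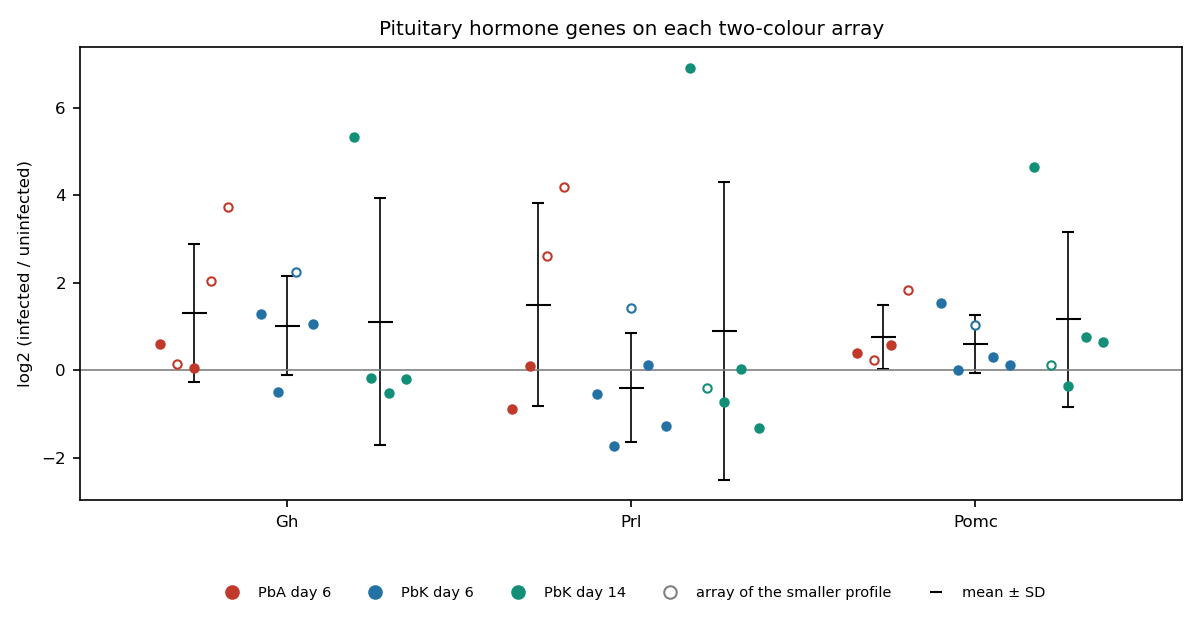
Log2 ratio (infected over uninfected) of the pituitary hormone genes Gh, Prl and Pomc on each spotted array with a value, with the mean and SD per group; open points are the 5 arrays that correlate with each other across groups. PbK day 14 replicate 1 stood apart for all 3 genes, at 5.33, 6.91 and 4.64.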

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

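Tests chosen only after the result was seen were those on the genes low in PbA day 6, on the absence of calls between PbA day 6 and PbK day 6, and on the pituitary genes. The counts over other splits of the arrays were planned.

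The 52 genes called at least 1 log2 unit lower in PbA day 6 on the spotted arrays had a median of -1.36 there. On the Affymetrix arrays the same genes had a median of -0.134 in PbA day 6 (95% bootstrap interval -0.205 to -0.0579), but the 90 genes called at least 1 log2 unit higher also went from 1.27 to 0.227 there, so the test leaves lower expression in the infected brain open. The 52 genes were also low in the other spotted groups, with medians of -0.679 in PbK day 6 and -1.09 in PbK day 14. A gene-specific effect of dye, probe or the shared reference is a candidate explanation, since without a dye swap it would lower the same genes in every group.

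No gene was called between PbA day 6 and PbK day 6 on the spotted arrays, whereas 268 genes stood at least 1 log2 unit higher and 46 lower between the Affymetrix samples, with the pituitary genes Gh (4.56) and Prl (4.54) highest. For 48 interferon and MHC class I genes of the lists fixed beforehand, the median difference was 1.36 between the Affymetrix samples. On the spotted arrays it was 0.146 (95% interval -0.342 to 0.653, arrays and genes resampled). This argues against spread between the spotted arrays alone hiding a difference of at least 1 on their own scale. A difference made smaller on that scale could still be hidden by the spread. Smaller ratios on the spotted arrays may account for the gap between platforms in part or in full: these 48 genes had spotted medians of 0.273, 0.438 and 0.324 of their Affymetrix medians in PbA day 6, PbK day 6 and PbK day 14. A biological difference between single samples on the Affymetrix arrays stays open and was not tested, since each group has 1 array.

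The pituitary hormone genes stood apart on PbK day 14 replicate 1, at 5.328 for Gh, 6.912 for Prl and 4.64 for Pomc. Over the spotted arrays, Pearson's r was 0.944 for Gh with Prl (n = 12), 0.885 for Gh with Pomc (n = 12) and 0.899 for Prl with Pomc (n = 13), with permutation p of 6e-05, 0.00057 and 0.00078 (adjusted over 3 relations 0.00018, 0.00078 and 0.00078). Spearman's rho was 0.818, 0.629 and 0.643, with permutation p of 0.0017, 0.033 and 0.02 (adjusted 0.0052, 0.033 and 0.031). Without PbK day 14 replicate 1 and PbA day 6 replicate 5, the arrays farthest from the median, r was 0.769, 0.553 and 0.43, so the strength of the relation rests on those arrays. Pituitary tissue carried into some brain samples may be the source, which stays open: it would raise these genes most on the arrays left out, so the lowest r of 0.43 does not decide, and no biological explanation was tested.

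Chance gives about 1 in 20 groups a sample this far from its others, and 10 of 149 groups of named-gene values, 6 of 81 groups of list medians and 1 of 9 groups of array measures had one. In PbA day 6, Fastkd3 was at -4.104 and Gjb6 at 1.247 on replicate 5, and Vcam1 was at 1.862 on replicate 2. In PbK day 6, Cavin2 was at -4.902 on replicate 1, and Irf8 was at 2.046 and Rpl7 at -1.993 on replicate 3. In PbK day 14, Apoc1 was at -5.768 and Slco1a4 at 0.3335 on replicate 2, and Mcm2 was at -0.3945 and Samd9l at -2.267 on replicate 3.

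Among list medians in PbK day 6, MHC class II genes were at 2.158 on replicate 3, iron and haem handling genes at -0.1313 on replicate 5 and immediate early genes at 0.2201 on replicate 4. In PbK day 14, interferon-stimulated genes were at 0.9412 and microglia and macrophage markers at 0.4867 on replicate 1, and neutrophil and monocyte markers at -0.3295 on replicate 2. The SD of log2 ratios was 1.311 on PbA day 6 replicate 1 and at most 0.8359 on the other arrays of that group.

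Differences between infected groups passed a direct test for 2 features and, at the preset correlation, for several lists. With an estimated correlation 0 of the 3 lists between PbK day 14 and PbK day 6 passed by cameraPR (3 at an unadjusted p under 0.05, 2 by fry), and 1 of the 6 between PbA day 6 and PbK day 14, the endothelial markers. Between PbK day 14 and PbK day 6 the differences were 4.387 for Hba-a1, 6.178 for spot 6784, 0.323 for glucocorticoid-responsive genes, -0.452 for heat-shock proteins and 0.14 for cytosolic ribosomal proteins. Between PbA day 6 and PbK day 14 they were -3.75 for Hba-a1, -5.782 for spot 6784, 0.564 for immediate early genes, 0.43 for heat-shock proteins and -0.378 for endothelial markers. They were 0.359 for cell cycle genes, 0.442 for interferon-stimulated genes and -0.0887 for cytosolic ribosomal proteins.

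Over 100 of the 126 splits of the same arrays, 2 splits, the real one included, matched or passed the 2 features called between PbK day 14 and PbK day 6. For the 2 features between PbA day 6 and PbK day 14, 3 splits did. Each share lies under 0.05 taken singly, without adjustment over the split counts read. The highest other counts were 39 and 3, both above the real 2, so the counts do not exclude chance. A split with 39 points to a structure of the samples. It put both arrays of these groups that belong to the set of 5 correlated arrays on one side, but other splits that did so gave 0 or 1, so the structure was not identified. For lists chance is not excluded either: 22 splits gave at least the 3 lists of PbK day 14 against PbK day 6 (highest other 6), and 7 gave at least the 6 of PbA day 6 against PbK day 14 (highest other 9). For PbA day 6 against PbK day 6, limma called 0 features (1403 at an unadjusted p under 0.05) and cameraPR 0 lists (4 at an unadjusted p under 0.05, 0 by fry), and any of the 100 splits gives at least 0, so the splits cannot test these counts. The highest other split gave 20 features and 7 lists.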

How the results depend on the processing

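Tests chosen only after the data were seen were a term for the set of 5 correlated arrays, group means within the other 10 arrays, the z-scores in every list test reported, the list tests with a block or without single arrays, and the Affymetrix ratios between infected samples. Where a value moved, the cause was not tested, except that a stricter threshold calls fewer features and no signal filter admits more genes.

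For PbA day 6 against control, 585 features became 1524 with array weights (930 higher, 594 lower), 60 at an adjusted p under 0.01, 1089 with the term for the correlated arrays, 3 within the other 10 arrays, and 0 by limma with only that group's arrays (3768 at an unadjusted p under 0.05). They became 590 with the replicate number as a block and 830 with quantile scaling, which put 458 higher and 372 lower (55.2% higher against 65.8%). Leaving out 1 array of the group gave 106 to 741. For PbK day 6, 98 features became 45 with quantile scaling (24 higher, 21 lower, 53.3% higher against 35.7%), 1083 with array weights, 27 without moderation of the variance, 7 at an adjusted p under 0.01, 627 with the term, 8 within the 10 arrays, 94 with the block, and 0 by limma with only that group's arrays (2267 at an unadjusted p under 0.05). Leaving out 1 array of the group gave 10 to 319. For PbK day 14, 129 features became 206 among features measured on all 15 arrays, 210 with array weights, 33 at an adjusted p under 0.01, 425 with the term, 16 with only that group's arrays and 128 with the block. Leaving out 1 array of the group gave 35 to 139.

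Between infected groups, PbA day 6 against PbK day 6 gave 0 by limma in every alternative run, the block included, with 700 to 2227 at an unadjusted p under 0.05. The 2 features of PbK day 14 against PbK day 6 became 1 with quantile scaling and 1 among features on all 15 arrays, and stayed 2 with the block. The 2 of PbA day 6 against PbK day 14 became 1 with quantile scaling and 0 by limma within the 10 arrays (559 at an unadjusted p under 0.05), and stayed 2 with the block. Leaving out 1 array of the groups compared gave 2 in both. Scaling the spread between arrays changed nothing, because the deposited arrays already share one median absolute log2 ratio. Their SDs of log2 ratios still ran from 0.686 to 1.311.

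The list test was first run on the moderated statistics themselves, which put 12 lists past the threshold in PbK day 14 against 9 with z-scores, 4 against 3 between PbK day 14 and PbK day 6, and 7 against 6 between PbA day 6 and PbK day 14. The other 3 comparisons had equal counts. With an estimated correlation the lists past the threshold went from 11 to 3 in PbA day 6, from 3 to 0 between PbK day 14 and PbK day 6 (3 at an unadjusted p under 0.05, 2 by fry) and from 6 to 1 between PbA day 6 and PbK day 14, where fry also gave 1. Leaving out 1 array of the groups compared gave 5 to 12 lists in PbA day 6, 0 to 2 between PbA day 6 and PbK day 6 and 3 to 7 between PbA day 6 and PbK day 14. No named called gene and no list past the threshold changed direction. Of the values of named called genes under alternatives, 201 of 884 in PbA day 6, 128 of 388 in PbK day 6 and 111 of 597 in PbK day 14 lost the call.

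On the Affymetrix arrays, without the signal filter the counts of genes at least 1 log2 unit apart were 2124, 1752 and 2128 over uninfected for PbA day 6, PbK day 6 and PbK day 14, 1925 for PbA day 6 over PbK day 6, 1944 for PbK day 14 over PbK day 6 and 2086 for PbA day 6 over PbK day 14. For PbK day 14 over PbK day 6 a pseudocount of 64 gave 124 and the mean of probe sets 302. List medians changed sign for T and NK cell markers in PbK day 6 (-0.0474) and neutrophil markers in PbA day 6 over PbK day 14 (-0.0464) without the filter. They did so with the mean of probe sets for astrocyte markers in PbK day 14 (-0.0449) and endothelial markers in PbA day 6 over PbK day 6 (0.0319).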

Other observations

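Several cell types and pathways have not been described so far, and none of their lists passed the threshold in an infected group against control on the spotted arrays. In PbA day 6, PbK day 6 and PbK day 14, complement genes had medians of 0.20, 0.12 and 0.29 (list adjusted p = 0.18, 0.634 and 0.117). T and NK cell markers had medians of 0.11, 0.11 and 0.14 (0.406, 0.523 and 0.0596), and neutrophil and monocyte markers 0.21, 0.01 and 0.05 (0.128, 0.41 and 0.211). B cell markers had medians of -0.03, -0.29 and 0.00 (0.981, 0.197 and 0.966), and the last turned to 0.02 with quantile scaling. Hypoxia and glycolysis genes had medians of 0.17, 0.11 and 0.11 (0.183, 0.523 and 0.0812), apoptosis genes 0.08, -0.10 and 0.13 (0.442, 0.843 and 0.225) and kynurenine pathway genes 0.07, -0.10 and -0.24 (0.907, 0.991 and 0.402). Iron and haem handling genes had medians of 0.04, 0.32 and 0.07 (0.981, 0.197 and 0.402), the first turning to -0.01 with quantile scaling. Oxidative phosphorylation genes had medians of -0.01, 0.08 and 0.02 (0.683, 0.197 and 0.68). Called members of these lists not named so far included, in PbA day 6, Plac8 (2.55 ± 0.581, 3 arrays with a value), Bid (0.66 ± 0.142), Bnip3 (0.44 ± 0.0953) and Blvrb (-1.14 ± 0.281). Bnip3 was also called in PbK day 14 (0.48 ± 0.0953). Each of these calls ended when some single array of its group was left out.

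On the Affymetrix arrays, with 1 array per group, some of these lists lay outside the middle 95% of random lists. Complement genes stood at 2.39, 0.876 and 1.45 over the uninfected sample, neutrophil and monocyte markers at 2.41, 0.90 and 1.27 and T and NK cell markers at 0.999, 0.411 and 0.578. Apoptosis genes stood at 0.929, 0.103 and 0.417, with the PbK day 6 value inside the random range. Meningeal and fibroblast genes, a list added after the values were seen, stood at -0.641 in PbA day 6 (random range -0.237 to 0.205), -0.157 in PbK day 6 and -0.218 in PbK day 14. Choroid plexus genes, also added afterwards, stood at -0.19, -0.136 and -0.058, inside the random range. Kynurenine pathway genes stood at 0.113, 0.159 and 0.379, inside it as well.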
